A study of Mus musculus with 12 samples.

How the data were processed

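RNA was extracted from Beko pre-T cells and ribosomal RNA-depleted libraries were made with a stranded total RNA kit, per the labels' protocols. The 12 libraries form 6 groups of 2: DAPT and its DMSO control, apicidin and its DMSO control, and shHdac3 and a scrambled hairpin. Groups and replicate numbers were taken from the submitters' sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The submitters' processing notes name the mm9 genome build and the tools FastQC, Bowtie2, TopHat and DESeq2, without versions or roles. The read counter, its gene annotation and its strand setting are not given in the sources used here.

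The authors deposited 1 table per experiment, each with 23366 gene symbols. Per the file headers, each deposited table holds, for each of 4 libraries, a normalized signal per gene, together with a mean signal, a log2 fold change with its standard error, and p-values with adjusted p-values. The deposited signal values are whole reads divided by 1 size factor per library, as shown by the values: 100% of them are whole multiples of the value of 1 read. Values within 1e-06 of a whole multiple, relative to it, were counted as whole. Each experiment was normalized on its own. All per-library columns could be matched to a sample. Whole reads were recovered from the step of each library, and the depths in the report are sums of these reads over gene symbols.

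The design fixed at the outset assumed raw counts and named limma for the case of normalized values, which is what the tables hold. The main test was therefore limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(value + 1), for genes with a value of 10 or more in at least 2 of the 4 libraries of the comparison. The test used only those 4 libraries, no covariates, and Benjamini-Hochberg adjustment at 0.05, and was two-sided. Every adjusted p in the report without another name is from this test. The pseudocount of 1 understates the fold change of genes with low values. Differences between responses were tested with limma on all 12 libraries in 6 groups, after recomputing size factors over the recovered reads, as the difference of 2 treated-against-control changes. Overlaps of calls were tested with Fisher's exact test, two-sided, beside the overlap that independent lists would give, and no 2 comparisons shared control libraries. Correlations across genes describe the libraries, since genes are not independent replicates; 3 pairs of comparisons were computed.

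The comparisons, their tests, the gene lists, the rule for named genes and part of the alternatives were written before the data were examined. The filter and the intensity trend of the limma test were not specified there and were set once the unit was known. Alternatives added later were the edgeR test on recovered reads, TMM factors, the authors' adjusted p and the fits without structural RNA genes. Other pseudocounts for single genes, upper-quartile factors for lists and DAPT sets, a stricter filter for the DAPT sets, the left-out libraries in the test of differences, and the camera tests of lists and sets on differences between experiments were also added later. The rule takes Hdac3, the Notch target genes that passed in any comparison, and Hes1, Dtx1, Nrarp, Ptcra, Il2ra, Myc and Notch3 whether or not they passed. It adds the 6 largest rises and 6 largest falls among genes that passed with a mean of 50 or more, both treated libraries on the same side of both controls and a curated symbol. From each other list described it takes up to 4 members with the largest change that passed, and for overlaps it takes the 6 genes with the smallest worst adjusted p. Not every gene that the rule allows is named, and the values of some are not reported here. There were 28 gene lists of known pathways, complexes and cell types, compiled by hand from general knowledge. Each was tested against all other genes with camera (limma), with a preset correlation of 0.01 and again with an estimated correlation, two-sided, and adjusted over the lists. The planned fry test (limma) was run beside it. It asks whether a list changed, without comparing the list with other genes. The DAPT-lowered and DAPT-raised sets are the genes past 0.05 in the DAPT experiment, tested in libraries that did not enter their choice. No other splits of the samples were counted, because groups of 2 allow too few.

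The scripts were tested on simulated reads for each comparison, with 50 genes at each of 4 fold sizes. For the DAPT comparison (12744 simulated genes tested), 68% of genes changed 1.25-fold, 86% at 1.5-fold, 94% at 2-fold and 98% at 4-fold were called in the right direction. For apicidin (12425 genes) these shares were 64%, 78%, 90% and 100%, and for shHdac3 (12578 genes) 52%, 74%, 85.7% and 100%. False calls among unchanged genes numbered 6, 8 and 4. The data held far more called genes, such as 5546 of 12840 tested with DAPT. The Benjamini-Hochberg cutoff depends on that share, so the simulated recovery and false calls do not carry over directly. In 200 random sets of simulated genes per comparison, camera gave p under 0.05 in 5, 11 and 5 sets with the preset correlation and in 0 with the estimated one. Genes were simulated independently, so these sets cannot show how the preset correlation behaves for correlated lists. In the data, the estimated correlation of ribosomal protein genes was 0.142, 0.775 and 0.962 with DAPT, apicidin and shHdac3. For replication-dependent histone genes it was 0.891, 0.956 and 0.983. Of 10 simulated sets raised 1.25-fold, camera called 10 with the preset and 0 with the estimated correlation in each comparison. No other shift was simulated. A list that does not pass with the estimated correlation may therefore still have shifted.

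Alternatives were other size factors (TMM and upper-quartile), other filters and pseudocounts, other thresholds, a fit of all 12 libraries, the replicate number as a block and each library left out in turn. When 1 library is left out, the lone library of its group is assumed to vary like the other group. Within 1 experiment such a fit has 1 residual degree of freedom, so a smaller p-value than in the full fit is no gain in evidence. The count tests edgeR (version 4.0.16, quasi-likelihood) and DESeq2 (version 1.42.0) were run on the recovered reads. The edgeR test called 2669 genes higher and 2901 lower with DAPT, 2279 and 2486 with apicidin, and 2839 and 2475 with shHdac3. Of these, 5455, 4644 and 5205 were called in the same direction by limma. In the authors' deposited tables, adjusted p under 0.05 marks 1646 genes higher and 2168 lower with DAPT, 1136 and 1329 with apicidin, and 1694 and 1267 with shHdac3. Of the 3814, 2465 and 2961 genes marked in the authors' deposited tables and tested here, 3797, 2459 and 2950 were also called here with the same sign and 0 with the opposite sign. Both treated libraries lay on the same side of both controls in 69.9%, 69.0% and 69.2% of tested genes, where chance gives 33.3%, and 13, 8 and 25 called genes lacked that separation.

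Transcript length and GC content were taken from the longest GENCODE M21 transcript of each symbol, of which 21732 matched directly and 1273 through a synonym. That annotation is on a newer build than mm9, so no coordinates are printed. Because strand use in counting is unknown, genes that overlap another gene are uncertain: 29 of 249 named genes share over 10% of their exonic bases with another gene of that annotation. Among those named in the text are Nrarp, Ccnd1, Spsb4, Ccr9, Lef1, Exoc3l4, Gpr65, Hmgcs1, Txnip, Ube2c, Dbp and Hdac11 on the opposite strand, and Itgam on the same strand. Replication-dependent histone genes have near-identical copies and their single values are uncertain. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.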

Results

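Gene expression was measured by RNA-seq of ribosomal RNA-depleted total RNA in Beko cells, a mouse line of pre-T cells, a stage of T cell development that depends on Notch signalling. The 12 libraries formed 3 experiments, each with 2 treated and 2 control libraries. In the first, cells received 10 µg/ml DAPT for 24 h or DMSO; DAPT inhibits γ-secretase, the protease that releases the Notch intracellular domain. In the second, cells received 0.01 µg/ml apicidin, a histone deacetylase inhibitor, for 24 h or DMSO. In the third, cells carried a short hairpin RNA against Hdac3 (shHdac3) or a scrambled hairpin and were harvested 96 h after puromycin addition. DAPT was used to find the genes that respond to loss of Notch signalling, and the other treatments to ask what HDAC3, a class I histone deacetylase, does at those genes. Levels are normalized reads, given as mean ± SD with n = 2 libraries per group, and log2 fold changes are given ± SE of the limma fit. The 3 experiments were normalized separately, so levels are compared only within an experiment.

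Reads assigned to genes ranged from 37237080 to 42815304 per library in the DAPT experiment, from 21766984 to 29652001 in the apicidin experiment and from 24673559 to 29004315 in the hairpin experiment. Replicate libraries correlated across tested genes with r of 0.995 to 0.997, and each pair differed by more than sampling noise, with a chi-square per degree of freedom of 3.47 to 19.0. Genes with symbols beginning Hist, which include replication-dependent histone genes whose mRNAs lack poly(A) tails, took 15.4% to 21.4% of the reads. The 45S pre-rRNA gene Rn45s took 2.08% and 2.55% with apicidin against 2.74% and 3.18% with DMSO. Its share was 2.19% and 2.03% with shHdac3 against 3.19% and 2.80% with the scrambled hairpin, and 1.39% and 1.55% with DAPT against 2.39% and 1.48% with DMSO.

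Hdac3 itself was examined first, since it is the gene targeted by the hairpin. Its level was 774 and 819 in the shHdac3 libraries and 2012 and 1930 in the scrambled libraries, a 2.47-fold reduction (log2 fold change -1.31 ± 0.05, adjusted p = 7.6e-25). In the DAPT experiment Hdac3 stood at 3368 ± 46.8 against 3565 ± 108 (-0.08 ± 0.04, adjusted p = 0.11), and passed without DMSO replicate 2 (-0.11, adjusted p = 0.025). With apicidin it was 2023 ± 22.2 against 2217 ± 63.2 (-0.13 ± 0.04, adjusted p = 0.027). That call was lost without apicidin replicate 1 (adjusted p = 0.15), apicidin replicate 2 (0.081) or DMSO replicate 2 (0.13).

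**Figure D1:**
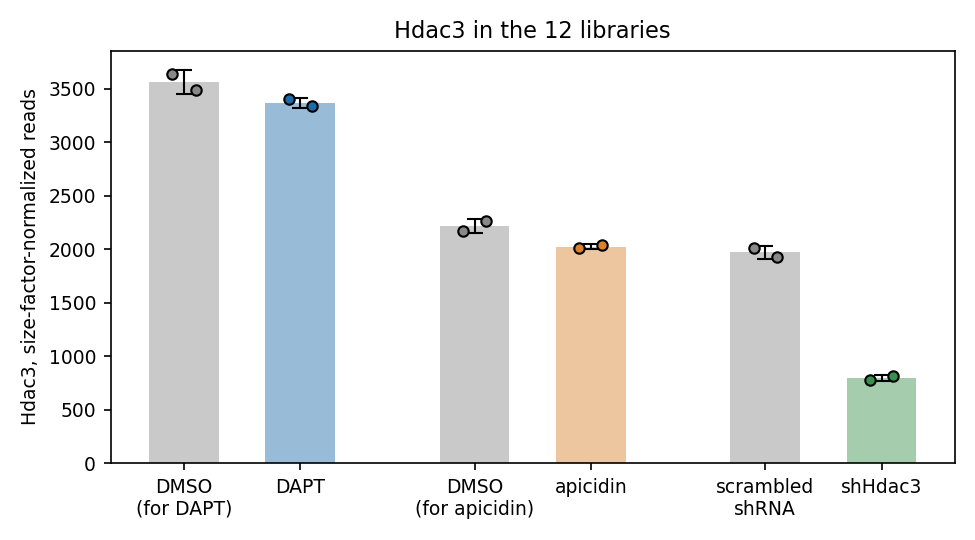
Level of Hdac3 in each of the 12 libraries, in size-factor-normalized reads, with points for libraries and bars for the mean of each group of 2. The shHdac3 libraries lie at 774 and 819 and the scrambled libraries at 2012 and 1930; levels are not comparable between the 3 experiments, which were normalized separately.

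Most measured Notch target genes fell after DAPT. Dtx1, a ubiquitin ligase of the Notch pathway, fell from 16224 ± 566 to 1952 ± 11.02 (-3.05 ± 0.04). Ptcra, which encodes the pre-T cell receptor alpha chain, fell from 7796 ± 142 to 1558 ± 38.9 (-2.32 ± 0.04). The transcriptional repressors Hey1 (-2.36 ± 0.05), Heyl (-2.36 ± 0.14) and Hes1 (-1.74 ± 0.09) fell as well. So did the IL-2 receptor alpha chain gene Il2ra (-1.78 ± 0.08), the receptors Notch1 (-1.27 ± 0.04) and Notch3 (-0.89 ± 0.04), the feedback regulator Nrarp (-1.10 ± 0.05) and the growth regulator Myc (-0.82 ± 0.04). In the annotation used here, 79.4% of the exonic bases of Nrarp overlap a gene on the opposite strand, whose reads cannot be told apart where counting ignores strand. Smaller falls were seen in Fjx1 (-0.75 ± 0.05), Shq1 (-0.62 ± 0.09) and Trib2 (-0.30 ± 0.04). In the same list, the T cell transcription factor genes Gata3 (0.75 ± 0.04), Tcf7 (0.41 ± 0.04) and Bcl11b (0.24 ± 0.04) rose, as did Lfng (0.79 ± 0.16), Ccnd1 (0.56 ± 0.04) and Il7r (0.36 ± 0.08). Igf1r was at -0.10 ± 0.06 (adjusted p = 0.19).

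Of the 22 Notch target genes listed, 20 were measured, 13 fell and 6 rose with DAPT, and the counts adjusted over the list alone were also 13 and 6. The list moved down against all other genes (median -0.79; camera adjusted p = 6.5e-06; adjusted p = 0.38 with an estimated correlation). Among 26 measured Notch pathway components, 8 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.39 with an estimated correlation). The coactivator gene Maml2 (0.83 ± 0.20) and the protease gene Adam10 (0.32 ± 0.04) were among them. This list call was lost with the replicate number as a block, and when DAPT replicate 1 or DAPT replicate 2 was left out.

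**Figure D2:**
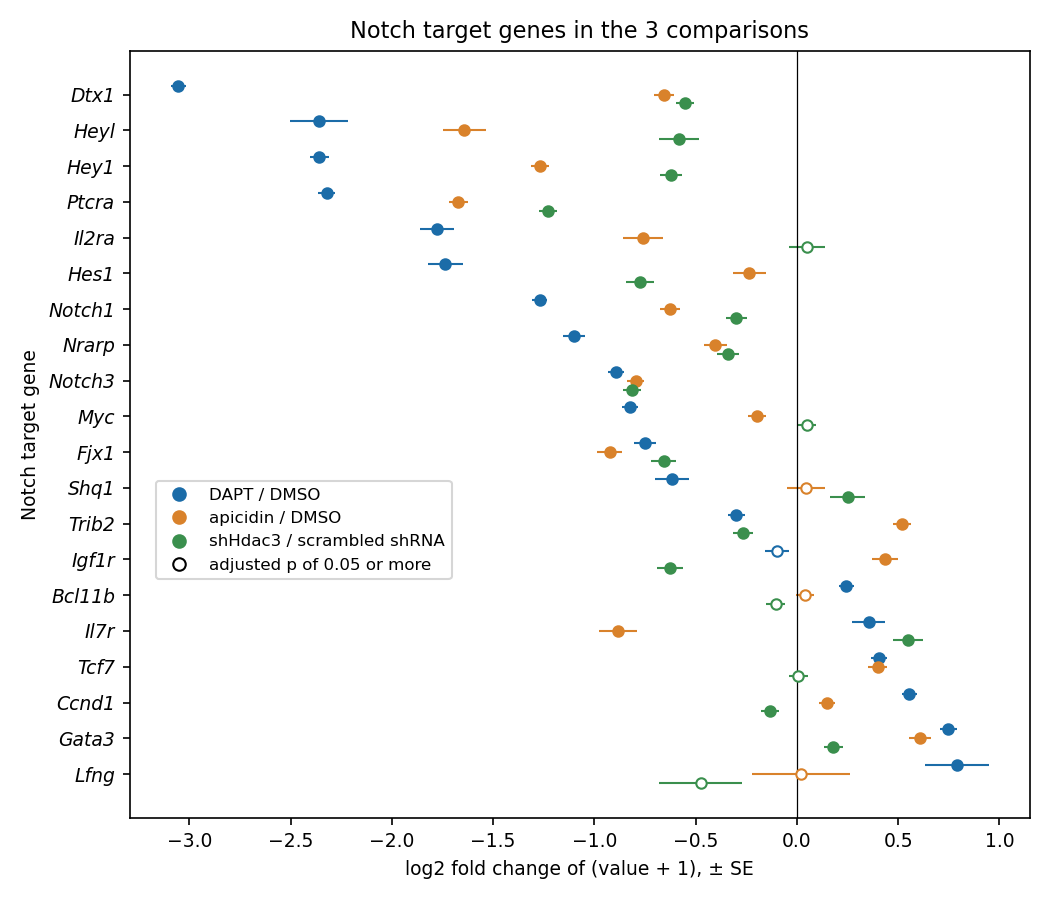
Log2 fold change ± SE of each measured Notch target gene with DAPT against DMSO, apicidin against DMSO and shHdac3 against the scrambled hairpin, 2 libraries per group. Dtx1 is at -3.05, -0.66 and -0.55 in the 3 comparisons, and Gata3 at 0.75, 0.61 and 0.18.

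Across the transcriptome, the largest falls with DAPT also included Ace, which encodes angiotensin-converting enzyme and went from 238 ± 10.0 to 1.53 ± 0.858. The fatty acid elongase gene Elovl3 (-3.77 ± 0.24), the E-cadherin gene Cdh1 (-3.31 ± 0.13), the kappa opioid receptor gene Oprk1 (-3.18 ± 0.06) and Spsb4 (-3.12 ± 0.14) followed. The largest rise was in the chemokine receptor gene Ccr9, from 463 ± 24.5 to 4077 ± 111 (3.14 ± 0.05). Other large rises were in Cilp (2.54 ± 0.12), Lztfl1 (2.42 ± 0.04), the IL-6 receptor gene Il6ra (2.27 ± 0.16) and the mast cell protease gene Cpa3 (2.16 ± 0.07). Of 12840 genes tested, 2584 were higher and 2962 lower at an adjusted p under 0.05, so 46.6% of calls were higher; with upper-quartile factors the counts were 3153 and 2430, or 56.5% higher. The median fold of these calls was 1.22, and 177 were higher and 124 lower by 2-fold or more.

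The lists of ribosome biogenesis and MYC, ribosomal protein, glycolysis and DNA replication genes moved down with DAPT. All 20 measured ribosome biogenesis and MYC genes fell, also adjusted over the list alone (median -0.63; camera adjusted p = 1.8e-20; adjusted p = 0.24 with an estimated correlation). They included the spermidine synthase gene Srm (-0.92 ± 0.05) and the nucleolar genes Mybbp1a (-0.79 ± 0.04), Rrs1 (-0.74 ± 0.05) and Ppan (-0.74 ± 0.05). Of 28 ribosomal protein genes, 26 fell and 0 rose, and 28 fell when adjusted over the list alone (camera adjusted p = 4.0e-06; adjusted p = 0.41 with an estimated correlation). Rps2 was the member with the largest fall (-0.35 ± 0.04). In glycolysis, 13 of 16 measured genes fell and 0 rose, with 14 falling when adjusted over the list alone (camera adjusted p = 9.8e-07; adjusted p = 0.38 with an estimated correlation); hexokinase 2, Hk2 (-0.49 ± 0.04), and Pgam1 (-0.45 ± 0.04) led it. Of 20 DNA replication genes, 14 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.39 with an estimated correlation).

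Heat shock and ATF4 stress genes moved down as lists with DAPT, and p53 target genes went both ways. Among 10 heat shock genes, 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0042; adjusted p = 0.39 with an estimated correlation); the mitochondrial chaperonin gene Hspd1 was at -0.74 ± 0.04. Of 15 ATF4 stress genes, 9 fell and 3 rose, likewise adjusted over the list alone (camera adjusted p = 0.0050; adjusted p = 0.45 with an estimated correlation). Asparagine synthetase, Asns (-0.88 ± 0.11), and the serine hydroxymethyltransferase gene Shmt2 (-0.61 ± 0.04) fell, while Ddit3, which encodes the transcription factor CHOP, rose (0.56 ± 0.08). Of 14 p53 target genes, 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (median 0.03; camera adjusted p = 0.46; adjusted p = 0.60 with an estimated correlation).

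Immediate early genes and markers of histone deacetylase inhibition moved up as lists with DAPT. Of 14 immediate early genes, 7 rose and 0 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0083; adjusted p = 0.45 with an estimated correlation), with the antiproliferative gene Btg2 at 0.70 ± 0.04. Of 9 genes known as markers of histone deacetylase inhibition, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 6.1e-04; adjusted p = 0.39 with an estimated correlation). Gsn (1.47 ± 0.04), Txnip (0.57 ± 0.04) and H1f0 (0.54 ± 0.04) rose and Clu fell (-1.53 ± 0.15). T lineage genes went both ways, 13 rising and 9 falling of 24, likewise adjusted over the list alone (camera adjusted p = 0.18; adjusted p = 0.45 with an estimated correlation). Cd5 rose (0.75 ± 0.14), while the recombinase gene Rag2 (-1.14 ± 0.07) and the transcription factor gene Lef1 (-0.99 ± 0.04) fell.

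Apicidin lowered a large part of the Notch target genes. Ptcra fell from 3612 ± 144 to 1133 ± 6.52 (-1.67 ± 0.05). Heyl (-1.64 ± 0.11), Hey1 (-1.27 ± 0.04), Fjx1 (-0.92 ± 0.06), Il7r (-0.88 ± 0.10), Notch3 (-0.80 ± 0.04), Il2ra (-0.76 ± 0.10), Dtx1 (-0.66 ± 0.05), Notch1 (-0.63 ± 0.05), Nrarp (-0.40 ± 0.06) and Myc (-0.20 ± 0.04) fell too. Hes1 was at -0.23 ± 0.08 (adjusted p = 0.027), a call lost without apicidin replicate 1 (adjusted p = 0.21) or DMSO replicate 2 (0.26). Gata3 (0.61 ± 0.05), Trib2 (0.52 ± 0.04), Igf1r (0.43 ± 0.07), Tcf7 (0.40 ± 0.05) and Ccnd1 (0.15 ± 0.04) rose; the Ccnd1 call was lost without apicidin replicate 1 (adjusted p = 0.066). Shq1 (0.05 ± 0.09), Bcl11b (0.04 ± 0.04) and Lfng (0.02 ± 0.24) did not pass. In all, 12 of 20 measured Notch target genes fell and 5 rose, likewise adjusted over the list alone (median -0.32; camera adjusted p = 0.0019; adjusted p = 0.72 with an estimated correlation).

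The largest falls with apicidin included Cdh1, from 322 ± 8.41 to 56.4 ± 3.89 (-2.50 ± 0.14), the purinergic receptor gene P2rx1 (-2.49 ± 0.18), Atoh8 (-2.24 ± 0.17), Exoc3l4 (-2.14 ± 0.09) and Rab44 (-2.03 ± 0.07). The largest rise was in Gimap4, one of a family of immune GTPase genes, from 48.4 ± 7.39 to 279 ± 32.5 (2.51 ± 0.16). The matrix metalloproteinase gene Mmp9 (2.09 ± 0.13), Gpr65 (1.60 ± 0.19), the activation marker gene Cd69 (1.55 ± 0.14), Lztfl1 (1.54 ± 0.05) and Gimap8 (1.53 ± 0.09) followed. Of 12463 genes tested, 2265 were higher and 2481 lower. The median fold of these calls was 1.23, and 103 were higher and 154 lower by 2-fold or more.

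Cholesterol synthesis genes, LXR and lipogenic genes and immediate early genes moved up as lists with apicidin. Of 20 cholesterol synthesis genes, 14 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.55 with an estimated correlation). The HMG-CoA synthase gene Hmgcs1 (0.61 ± 0.05), the squalene epoxidase gene Sqle (0.51 ± 0.04), Sc4mol (0.47 ± 0.05) and Mvd (0.46 ± 0.06) rose most. Of 11 LXR and lipogenic genes, 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 3.5e-04; adjusted p = 0.55 with an estimated correlation), with Mylip at 0.48 ± 0.07 and the fatty acid synthase gene Fasn at 0.37 ± 0.05. Of 14 immediate early genes, 6 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.55 with an estimated correlation), with Ier2 at 0.68 ± 0.08 and Junb at 0.66 ± 0.06. Glycolysis genes had 5 rising and 1 falling of 17, or 6 and 1 adjusted over the list alone. That list did not pass (camera adjusted p = 0.078, or 0.61 with an estimated correlation). Hk2 (0.78 ± 0.04) and the glucose transporter genes Slc2a3 (0.64 ± 0.05) and Slc2a1 (0.58 ± 0.05) were the leading rises.

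Ribosomal protein, ribosome biogenesis and MYC, mitosis and MHC class I genes moved down as lists with apicidin. Of 28 ribosomal protein genes, 23 fell and 0 rose, or 24 and 0 adjusted over the list alone (camera adjusted p = 1.5e-07; adjusted p = 0.72 with an estimated correlation), with Rps20 at -0.40 ± 0.05. Of 20 ribosome biogenesis and MYC genes, 10 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 0.0032; adjusted p = 0.55 with an estimated correlation). Of 20 mitosis genes, 10 fell and 0 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.55 with an estimated correlation), with the ubiquitin-conjugating enzyme gene Ube2c at -0.55 ± 0.04 and Cdc20 at -0.39 ± 0.04. Of 20 DNA replication genes, 7 fell and 2 rose, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.29; adjusted p = 0.71 with an estimated correlation). Of 13 MHC class I genes, 8 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.0081; adjusted p = 0.55 with an estimated correlation). The immunoproteasome genes Psmb10 (-0.69 ± 0.06) and Psme2 (-0.45 ± 0.06) fell and H2-D1 rose (0.39 ± 0.07).

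Markers of histone deacetylase inhibition went both ways with apicidin. Of 9 measured, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.38; adjusted p = 0.77 with an estimated correlation). The list median was -0.13, whereas its mean was 0.03 and the test direction was up. Without DMSO replicate 1 the list median was -0.17, and without DMSO replicate 2 it was -0.03. Gsn (0.86 ± 0.04), Txnip (0.77 ± 0.04) and H1f0 (0.64 ± 0.05) rose, and the cyclin-dependent kinase inhibitor gene Cdkn1a fell (-0.76 ± 0.08). Among T lineage genes, 8 rose and 9 fell of 24, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.82; adjusted p = 0.83 with an estimated correlation). Rag2 (-1.001 ± 0.08) and Rag1 (-0.92 ± 0.05) fell, and the costimulatory receptor gene Cd28 rose (0.81 ± 0.05). Of 5 measured NK and cytotoxic genes, 3 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.55 with an estimated correlation). These were the granzyme gene Gzma (1.02 ± 0.05), the perforin gene Prf1 (1.04 ± 0.21) and Tbx21 (1.10 ± 0.24), of which Gzma stood at 12628 ± 145 in the DMSO libraries.

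Knockdown of Hdac3 lowered 12 of 20 measured Notch target genes, without a change in Il2ra or Myc that passed the test. Ptcra fell from 6872 ± 153 to 2934 ± 30.3 (-1.23 ± 0.04). Notch3 (-0.81 ± 0.04), Hes1 (-0.78 ± 0.07), Fjx1 (-0.66 ± 0.06), Igf1r (-0.63 ± 0.06), Hey1 (-0.62 ± 0.05), Heyl (-0.58 ± 0.10), Dtx1 (-0.55 ± 0.05), Nrarp (-0.34 ± 0.06), Notch1 (-0.30 ± 0.05) and Trib2 (-0.27 ± 0.05) fell too. Il7r (0.55 ± 0.07) and Gata3 (0.18 ± 0.05) rose. Ccnd1 was at -0.13 ± 0.05 (adjusted p = 0.014), a call lost without shHdac3 replicate 2 (adjusted p = 0.099) or scrambled replicate 2 (0.12). Shq1 was at 0.25 ± 0.09 (adjusted p = 0.019), a call lost without shHdac3 replicate 1 (adjusted p = 0.21) or scrambled replicate 1 (0.12). Il2ra (0.05 ± 0.09), Myc (0.05 ± 0.05), Tcf7 (0.01 ± 0.05), Bcl11b (-0.10 ± 0.05) and Lfng (-0.47 ± 0.20) did not pass. Bcl11b passed without scrambled replicate 1 (-0.15, adjusted p = 0.029), and Lfng without shHdac3 replicate 2 (-0.63, adjusted p = 0.025) or scrambled replicate 1 (-0.67, adjusted p = 0.041). Of 20 measured Notch target genes, 12 fell and 3 rose, or 14 and 3 adjusted over the list alone (median -0.32; camera adjusted p = 2.9e-06; adjusted p = 0.37 with an estimated correlation).

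The largest falls after Hdac3 knockdown included the dynamin gene Dnm1, from 307 ± 12.3 to 50.3 ± 13.0 (-2.61 ± 0.16), Dennd5a (-2.39 ± 0.24), Clu (-2.16 ± 0.17), the sodium channel subunit gene Scn4b (-2.06 ± 0.06) and Elovl3 (-1.99 ± 0.16). The largest rise was in the adhesion receptor gene Gpr97, from 90.6 ± 6.84 to 445 ± 0.0887 (2.29 ± 0.12). Cd93 (1.76 ± 0.09), Gimap4 (1.74 ± 0.14), the integrin gene Itga4 (1.58 ± 0.08), Cpa3 (1.33 ± 0.05) and Mtss1l (1.29 ± 0.23) followed. Of 12482 genes tested, 2811 were higher and 2417 lower, so 53.8% of calls were higher; with upper-quartile factors this share was 43.5%. The median fold of calls was 1.22. By 2-fold or more, 42 genes were higher and 330 lower, 88.7% of them lower, and among genes at 500 or more these counts were 5 and 31.

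Ribosome biogenesis and MYC, DNA replication, mitosis and heat shock genes moved up as lists after Hdac3 knockdown. No list test, up or down, in any experiment was corrected for a trend with expression level or transcript length. With shHdac3, level and length explained 11.6% of the variance of log2 fold changes, and their part in these list shifts was not tested. All 20 measured ribosome biogenesis and MYC genes rose, also adjusted over the list alone (median 0.36; camera adjusted p = 5.6e-14; adjusted p = 0.37 with an estimated correlation), with Nop2 at 0.57 ± 0.05 and Mybbp1a at 0.46 ± 0.05. Of 20 DNA replication genes, 16 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 6.6e-09; adjusted p = 0.37 with an estimated correlation). The licensing factor gene Cdc6 (0.46 ± 0.04) and the helicase subunit gene Mcm3 (0.46 ± 0.04) led them. Of 20 mitosis genes, 11 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.37 with an estimated correlation), a list call lost without scrambled replicate 2 (adjusted p = 0.080). Of 10 heat shock genes, 6 rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.0088; adjusted p = 0.49 with an estimated correlation), with Hsph1 at 0.46 ± 0.05.

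The lists of p53 targets, immediate early, glycolysis and circadian clock genes and markers of histone deacetylase inhibition moved down after Hdac3 knockdown. Of 14 p53 target genes, 9 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 1.6e-04; adjusted p = 0.37 with an estimated correlation), with Cdkn1a at -1.50 ± 0.08 and the proapoptotic gene Bbc3 at -1.10 ± 0.13. Of 13 immediate early genes, 10 fell and 0 rose, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.0e-05; adjusted p = 0.37 with an estimated correlation), with Fos at -1.25 ± 0.23 and Ier3 at -1.20 ± 0.16. Of 16 glycolysis genes, 11 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 4.0e-05; adjusted p = 0.37 with an estimated correlation), with Slc2a1 at -0.87 ± 0.06. Of 12 circadian clock genes, 6 fell and 0 rose, likewise adjusted over the list alone (camera adjusted p = 9.3e-04; adjusted p = 0.37 with an estimated correlation), with Dbp at -1.46 ± 0.11 and Per3 at -1.09 ± 0.10. Of 9 markers of histone deacetylase inhibition, 6 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 6.0e-05; adjusted p = 0.37 with an estimated correlation). Clu (-2.16 ± 0.17) and Txnip (-1.04 ± 0.05) fell and Tubb3 rose (0.44 ± 0.08). T lineage genes went both ways, 7 rising and 8 falling of 24, likewise adjusted over the list alone (camera adjusted p = 0.44; adjusted p = 0.65 with an estimated correlation), with Cd4 at -1.22 ± 0.05.

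**Figure D3:**
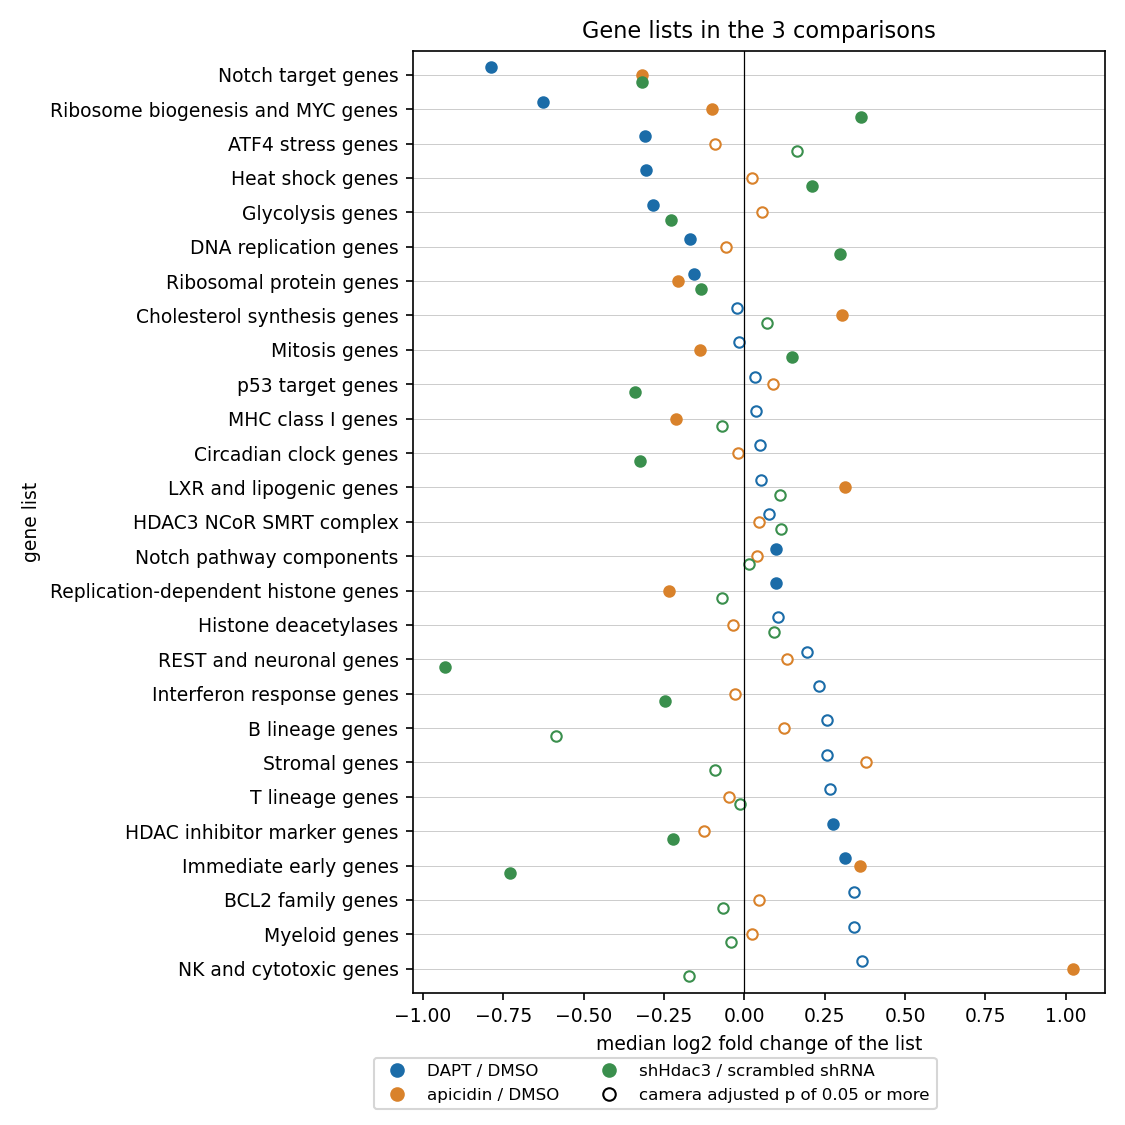
Median log2 fold change of each gene list in the 3 comparisons, with filled points where the camera adjusted p with a preset correlation is under 0.05 and open points elsewhere. Ribosome biogenesis and MYC genes have medians of -0.63 with DAPT, -0.10 with apicidin and 0.36 with shHdac3; with upper-quartile factors the sign of the median flips for mitosis and cholesterol synthesis genes with DAPT and for Notch pathway components with shHdac3, all open points.

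The genes that fell with DAPT were then followed in the HDAC3 experiments. With apicidin, 911 of 2949 measured DAPT-lowered genes fell and 353 rose (median -0.07; camera p = 1.9e-05; p = 0.13 with an estimated correlation). Of the DAPT-raised genes, 816 of 2547 rose and 486 fell with apicidin (median 0.07; camera p = 6.3e-04; p = 0.096 with an estimated correlation). With shHdac3 the DAPT-lowered genes as a whole went the other way, 461 of 2950 falling and 1160 rising (median 0.09, and 0.05 with upper-quartile factors; camera p = 3.0e-05; p = 0.23 with an estimated correlation). Of the DAPT-raised genes, 531 of 2534 rose and 744 fell with shHdac3 (median -0.04, and -0.08 with upper-quartile factors; camera p = 0.035, but 0.053 without shHdac3 replicate 1 and 0.076 without scrambled replicate 2; p = 0.21 with an estimated correlation).

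The DAPT-lowered genes as a whole had lower log2 fold changes with apicidin than with shHdac3 (median difference -0.15; camera p = 2.8e-13; p = 0.016 with an estimated correlation). Of the 113 measured genes that DAPT lowered by 2-fold or more, such as Ptcra, Hey1, Heyl and Dtx1, 68 fell and 3 rose with apicidin (median -0.62; camera p = 1.5e-20; p = 0.0054 with an estimated correlation). With shHdac3, 58 of these 113 fell and 10 rose (median -0.43; camera p = 1.1e-10; p = 0.077 with an estimated correlation). Among genes lowered by less than 0.25 on the log2 scale, 401 of 1371 fell and 194 rose with apicidin, and 200 of 1371 fell and 543 rose with shHdac3. Of those lowered by 0.5 to 1, 147 of 358 fell and 27 rose with apicidin (median -0.14). With shHdac3, 71 of 359 of them fell and 153 rose (median 0.14), so only the 2-fold lowered genes went down as a group. The genes that DAPT raised by 2-fold or more had 51 of 140 rising and 10 falling with apicidin (median 0.35; camera p = 1.7e-08; p = 0.013 with an estimated correlation). With shHdac3, 37 of 132 rose and 38 fell (median -0.01, test direction up; camera p = 0.58; p = 0.63 with an estimated correlation).

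**Figure D4:**
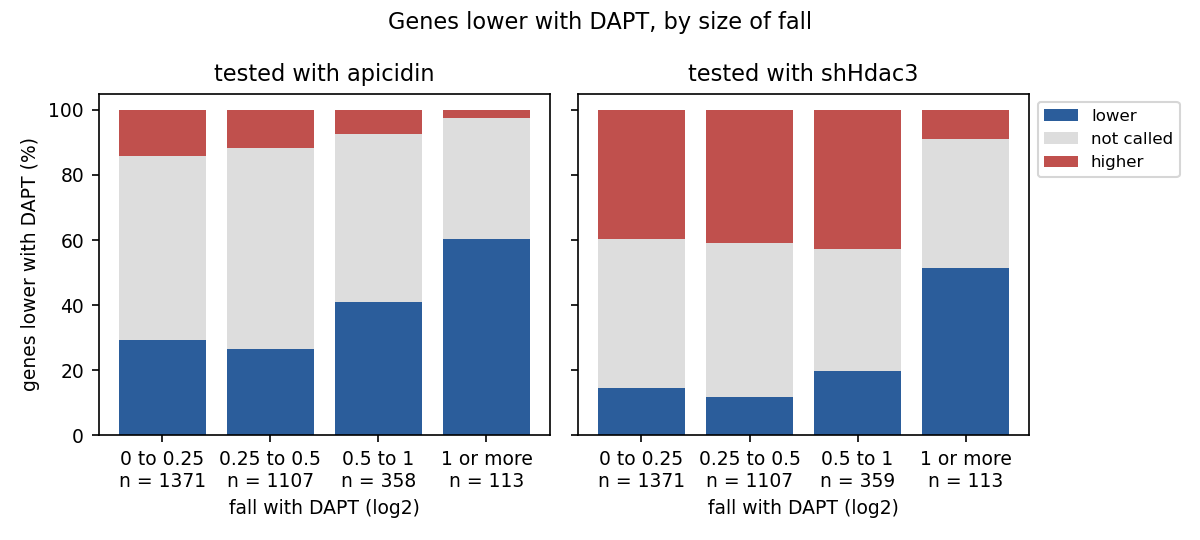
Share of DAPT-lowered genes, in percent, that were lower, higher or not past an adjusted p of 0.05 with apicidin and with shHdac3, grouped by the size of the log2 fall with DAPT. In the group that fell by 1 or more, 68 of 113 genes were lower with apicidin and 58 of 113 with shHdac3.

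Some genes changed the same way in all 3 experiments. Ptcra, Hey1, the nerve growth factor receptor gene Ngfr (-1.52 ± 0.05 with DAPT, -1.94 ± 0.08 with apicidin and -1.25 ± 0.05 with shHdac3), Exoc3l4 (-2.98 ± 0.08, -2.14 ± 0.09 and -1.72 ± 0.07), Cdh23 and Scn4b were lower in each. Lztfl1 (2.42 ± 0.04, 1.54 ± 0.05 and 0.79 ± 0.06), Ccr9 (3.14 ± 0.05, 1.21 ± 0.05 and 1.23 ± 0.08), Gzma, the glucocorticoid receptor gene Nr3c1 and the transferrin receptor gene Tfrc were higher in each. Of 12204 genes tested in all 3 experiments, 275 were lower in each, against 115 for independent lists, and 287 were higher in each, against 106. Rasal1 and Bst1 were among the genes lower with both DAPT and shHdac3, and Uaca and Aldh1b1 among those lower with both DAPT and apicidin.

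Apicidin and Hdac3 knockdown shared more calls than independent lists would. They shared 875 lower genes against 475 (odds ratio 3.07, Fisher's exact p = 2.4e-103) and 856 higher genes against 515 (odds ratio 2.54, Fisher's exact p = 2.4e-73). DAPT and apicidin shared 911 lower genes against 591 (odds ratio 2.24, Fisher's exact p = 1.1e-59) and 816 higher genes against 463 (odds ratio 2.76, Fisher's exact p = 4.1e-83). DAPT and shHdac3 shared 461 lower genes against 571 (odds ratio 0.72, Fisher's exact p = 2.5e-09), while 1160 genes were lower with DAPT and higher with shHdac3 against 668 (odds ratio 3.07, Fisher's exact p = 2.8e-125). Genes are not independent replicates in these tests. Expression level and transcript length explained 11.6% of the variance of log2 fold changes with shHdac3 and 2.23% with apicidin. Neither these overlaps nor the correlations that follow were corrected for that trend. Across genes, log2 fold changes correlated with Pearson r of 0.27 between DAPT and apicidin (Spearman rho 0.21), -0.06 between DAPT and shHdac3 (rho -0.17) and 0.26 between apicidin and shHdac3 (rho 0.20).

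The responses also differed. Notch target genes as a list fell more with DAPT than with apicidin (median difference -0.65, camera adjusted p = 1.1e-04, or 0.21 with an estimated correlation). The same held against shHdac3 (-0.48, camera adjusted p = 0.0098, or 0.23 with an estimated correlation). Between apicidin and shHdac3 the list did not pass (-0.08, camera adjusted p = 0.73, or 0.85 with an estimated correlation). Ribosome biogenesis and MYC genes fell with DAPT and rose with shHdac3 (median difference -0.98; camera adjusted p = 5.9e-22; adjusted p = 0.0087 with an estimated correlation). Hk2 and Slc2a1 rose with apicidin (0.78 ± 0.04 and 0.58 ± 0.05) and fell with shHdac3 (-0.50 ± 0.06 and -0.87 ± 0.06), and the differences were 1.28 ± 0.06 and 1.45 ± 0.07. Il7r fell with apicidin (-0.88 ± 0.10) and rose with shHdac3 (0.55 ± 0.07), a difference of -1.43 ± 0.11. A direct test of the difference of log2 fold changes, in a fit of all 12 libraries, called 4359 of 13042 genes between apicidin and shHdac3. Of these, 728 were called in opposite directions in the separate experiments. The test called 4541 genes between DAPT and apicidin and 5714 between DAPT and shHdac3. These differences compare changes against each experiment's own controls, in a fit with size factors computed over all 12 libraries together. They were not corrected for a trend with expression level or transcript length.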

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

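The level, length and GC tests of the DAPT-lowered sets in the shHdac3 experiment were chosen only after the result was seen: the earlier prediction was for a fall of the whole set, and the tests were rewritten when the set rose; the camera tests of lists on differences between experiments, and the fits of single differences with 1 library left out, were also outside the fixed design. The single genes, gene lists and counts of differing genes were singled out because a direct test found that a change differed between experiments, for the Notch target genes and the lists where the experiments also called them in opposite directions, and the DAPT-lowered sets and the Gimap family because of their values.

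Genes lowered by DAPT fell as a set with apicidin and rose as a set with shHdac3, while the 2-fold lowered ones fell with both. Of these 4, with an estimated correlation, only the fall of the 2-fold set with apicidin passed (p = 0.0054), against p = 0.13 for the whole set with apicidin, p = 0.23 with shHdac3 and p = 0.077 for the 2-fold set with shHdac3. After a fit of log2 fold change on expression level and transcript length, the difference from other genes went from -0.0970 to -0.0754 with apicidin, below the lowest of 1000 random sets (-0.0206), and after a fit on GC content it was -0.101. For the 2-fold lowered set with shHdac3 it went from -0.432 to -0.365 (lowest random set -0.0843) and to -0.398 after GC, so neither correction removed the falls. For the whole set with shHdac3, it went from 0.125 to 0.0584 after level and length, above the highest random set (0.0194), and to 0.113 after GC, so a level or length trend is a candidate source of the larger part of the rise, though the trend may itself be an effect of the knockdown.

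Apicidin and shHdac3 changed partly different genes: 4359 of 13042 genes differed between them, 4541 between DAPT and apicidin and 5714 between DAPT and shHdac3. Replicate noise alone would leave a correlation near 1 once corrected for standard errors. Among genes at 500 or more in both experiments the corrected correlation was 0.350, so noise between replicate libraries alone is not the cause. Between DAPT and apicidin it was 0.353. If the replicates are technical, the standard errors leave out variation between cultures, which the correction then cannot exclude. Apicidin was given for 24 h, cells with the hairpin were harvested 96 h after puromycin addition, and apicidin acts on other deacetylases. By their labels both shHdac3 libraries carried the same hairpin, so other effects of that hairpin cannot be told apart from loss of Hdac3. Hdac3 mRNA was reduced rather than absent (log2 fold change -1.31). These explanations stay open and were not tested.

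All 8 measured Gimap genes rose with apicidin, from Gimap9 (0.47 ± 0.06) to Gimap4 (2.51 ± 0.16). With shHdac3, 6 rose and 2 did not pass, and with DAPT, 4 rose and 4 did not pass. These family members were examined together after Gimap4 and Gimap8 were seen among the largest rises. The sequences argue against reads shared between paralogs, since the least distinct of these genes, Gimap3, has 92.5% of its 50-base stretches in no other Gimap gene. Joint regulation of the family is a candidate explanation, a hypothesis that was not tested.

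Differences are given as the log2 fold change in the first experiment named minus that in the second. Il7r differed by -1.43 ± 0.11 between apicidin and shHdac3 and by 1.23 ± 0.11 between DAPT and apicidin. Trib2 differed by 0.79 ± 0.06 between apicidin and shHdac3 and by -0.83 ± 0.06 between DAPT and apicidin. Igf1r differed by 1.06 ± 0.09 between apicidin and shHdac3. Ccnd1 differed by 0.29 ± 0.05 between apicidin and shHdac3 and by 0.68 ± 0.05 between DAPT and shHdac3. Shq1 differed by -0.87 ± 0.14 between DAPT and shHdac3. With shHdac3, the call of Ccnd1 was lost without shHdac3 replicate 2 (adjusted p = 0.099) or scrambled replicate 2 (0.12), and that of Shq1 without shHdac3 replicate 1 (0.21) or scrambled replicate 1 (0.12).

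Between apicidin and shHdac3, the median difference was -0.45 for ribosome biogenesis and MYC genes (camera adjusted p = 6.9e-16; adjusted p = 0.014 with an estimated correlation). It was -0.27 for mitosis genes (1.6e-07; adjusted p = 0.12 with an estimated correlation) and 1.03 for immediate early genes (9.2e-08; adjusted p = 0.071 with an estimated correlation). Lists whose difference passed with both correlations, without opposite calls, were added after their values were seen: DNA replication genes between apicidin and shHdac3 (-0.40, 6.7e-10; adjusted p = 0.010 with an estimated correlation) and ribosome biogenesis and MYC genes between DAPT and apicidin (-0.50, 1.8e-15; adjusted p = 0.030 with an estimated correlation). Between DAPT and apicidin the median difference was 0.29 for replication-dependent histone genes (camera adjusted p = 6.7e-07, and 0.48 with an estimated correlation). In the apicidin experiment, DMSO replicate 2 had 20.3% of its reads in genes with symbols beginning Hist. The other 3 libraries of that experiment had 17.0% to 17.9%. Without DMSO replicate 2 the median difference was 0.19. Between DAPT and shHdac3 it was -0.98 for ribosome biogenesis and MYC genes (5.9e-22; adjusted p = 0.0087 with an estimated correlation), -0.47 for DNA replication genes (3.9e-08; adjusted p = 0.0087 with an estimated correlation) and -0.48 for heat shock genes (9.5e-04; adjusted p = 0.066 with an estimated correlation). In the same contrast it was 0.63 for markers of histone deacetylase inhibition (1.1e-05; adjusted p = 0.066 with an estimated correlation) and 0.72 for immediate early genes (2.2e-05; adjusted p = 0.11 with an estimated correlation).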

How the results depend on the processing

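The DESeq2, 2-fold, 0.01 and block alternatives were planned; edgeR, TMM on recovered reads, the authors' p-values, the fits without structural RNA genes, other pseudocounts for single genes, upper-quartile factors for lists and sets, a stricter filter for sets and left-out libraries for differences between experiments were chosen after seeing the data. Over 19 main results, 220 of 258 alternatives left the direction and the call as they were or a count within 1.5 times. DESeq2 on recovered reads gave 1650 higher genes for DAPT, 1135 higher and 1326 lower for apicidin, and 1695 and 1270 for shHdac3. The authors' deposited table gave 1646, 1136 and 1329, and 1694 and 1267. Requiring 2-fold left 177 higher and 124 lower, 103 and 154, and 42 and 330. An adjusted p under 0.01 left 1503 higher genes for apicidin and 2840 genes differing between apicidin and shHdac3. Calls shared by apicidin and shHdac3 were 564 lower and 529 higher at 0.01, 404 and 384 with DESeq2, and 48 and 6 at 2-fold. The lower counts at 0.01 and at 2-fold follow from the stricter threshold; for those with DESeq2 and in the authors' deposited table the cause was not tested.

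With an estimated correlation, the Notch target list lost its call (median -0.79, adjusted p = 0.38 with DAPT; -0.32, 0.72 with apicidin; -0.32, 0.37 with shHdac3). So, with an estimated correlation, did the DAPT-lowered and DAPT-raised sets, with apicidin (-0.067, p = 0.13; 0.070, p = 0.096) and with shHdac3 (0.094, p = 0.23; -0.043, p = 0.21). With camera at its preset correlation, the lowered set with shHdac3 reversed when taken at 2-fold (-0.43, p = 1.1e-10) and lost its call as the 200 smallest p (0.17, p = 0.11). At that preset correlation the raised set lost its call at adjusted p under 0.01 (-0.030, p = 0.080) and its test turned upward at 2-fold (-0.0091, p = 0.58) and as the 200 smallest p (0.086, p = 0.17). Leaving out 1 library moved the raised set between -0.0444 and -0.0382. For stromal genes with shHdac3 the fry test pointed up against a median of -0.090 (adjusted p = 0.046). For these the cause was not tested.

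Replicate differences in treated and control groups hardly correlated across tested genes (r = 0.019, 0.039 and 0.011 with DAPT, apicidin and shHdac3). Noise of genes with low values can hide a shared deviation, so whether replicates with the same number were made together stays unknown. The replicate block gave 2826 higher and 3152 lower genes with DAPT, 2294 and 2517 with apicidin, and 2861 and 2466 with shHdac3. The block ended no main call, gained 1 named gene and moved 3 other list calls. These were Notch pathway components (0.093) and NK genes (5.2e-06) with DAPT and glycolysis (0.042) with apicidin. A block fit of 4 libraries has 1 residual degree of freedom and leans on variance shared over genes. For Hdac3 with shHdac3 its limma adjusted p went from 7.6e-25 to 5.7e-114. Calls kept or gained with the block are therefore weak evidence that they hold.

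For the other lists, 698 of 775 alternatives left the call, 31 gained it, 45 lost it and 1 reversed. For named genes, 5864 of 6081 left it, 12 gained it and 205 lost it, 46 of these with DESeq2 and 44 with the authors' deposited adjusted p; 0 reversed. For 23 single differences between experiments, 184 of 184 fits with 1 library left out kept the direction. These differences were chosen because they passed in the fit of all 12 libraries. The left-out fits are therefore no separate check of their calls. Depth was lowest in the apicidin experiment, at 21766984 to 29652001 reads per library, which limits genes with low values most.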

Other observations

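Of the tests in this part, the upper-quartile value of the REST list was chosen only after the result was seen. Genes outside the T lineage and of further pathways were counted as well. After Hdac3 knockdown, interferon response genes had 6 falling and 1 rising of 16, likewise adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.37 with an estimated correlation). Among them, Ifi27l2a fell (-1.83 ± 0.18). The list had 6 rising and 2 falling of 16 with DAPT, likewise adjusted over the list alone, and 4 and 3 of 14 with apicidin, or 4 and 4 (camera adjusted p = 0.18 and 0.96; adjusted p = 0.45 and 0.97 with an estimated correlation). Its median and mean differ in sign with apicidin (-0.03 and 0.01, test down). Of 6 measured REST and neuronal genes, 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.37 with an estimated correlation), among them Unc13a (-1.49 ± 0.18) and Kcnh2 (-1.08 ± 0.09); the list call was lost without scrambled replicate 2 (adjusted p = 0.11) and with upper-quartile factors (0.074). With DAPT 4 of 8 rose and 0 fell, and with apicidin 1 of 7 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.16 and 0.66; adjusted p = 0.56 and 0.77 with an estimated correlation). Of 28 ribosomal protein genes, 14 fell and 0 rose, or 16 and 0 adjusted over the list alone (camera adjusted p = 9.9e-05; adjusted p = 0.65 with an estimated correlation), with Rpl22 at -0.35 ± 0.05; the list call was lost without scrambled replicate 1 (adjusted p = 0.051). Of 15 ATF4 stress genes, 7 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.091; adjusted p = 0.38 with an estimated correlation), with Slc7a5 at 0.58 ± 0.04 and Ddit4 at -1.19 ± 0.05. With apicidin, 3 of 14 p53 target genes rose and 3 fell, 3 of 14 ATF4 stress genes rose and 6 fell, and 1 of 10 heat shock genes rose and 2 fell, likewise adjusted over the lists alone (camera adjusted p = 0.63, 0.50 and 0.87; adjusted p = 0.77, 0.77 and 0.89 with an estimated correlation).

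Hdac5 rose with apicidin (1.51 ± 0.11) and with shHdac3 (0.89 ± 0.12), and Hdac11 fell with shHdac3 (-0.97 ± 0.15). Of the 11 histone deacetylase genes, Hdac3 included, 4 rose and 1 fell with DAPT, 3 and 2 with apicidin, and 2 and 3 with shHdac3; adjusted over the list alone these were 5 and 1, 3 and 2, and 2 and 3. Hdac3 is 1 of the falls with apicidin and with shHdac3. The list test did not pass with camera in any comparison (camera adjusted p = 0.41, 0.63 and 0.64; adjusted p = 0.56, 0.77 and 0.77 with an estimated correlation). Its median and mean differ in sign with apicidin (-0.03 and 0.10, test up) and with shHdac3 (0.09 and -0.09, test down). Replication-dependent histone genes had 13 of 27 falling with apicidin, 17 adjusted over the list alone (camera adjusted p = 3.5e-04; adjusted p = 0.77 with an estimated correlation), a call lost without DMSO replicate 2 (adjusted p = 0.16). With DAPT 10 rose, 5 adjusted over the list alone (camera adjusted p = 0.0035; adjusted p = 0.62 with an estimated correlation), a call lost without DAPT replicate 1 (adjusted p = 0.32) or DMSO replicate 2 (0.067). With shHdac3 1 rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.21; adjusted p = 0.91 with an estimated correlation).

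Markers of other cell types were mostly below the minimum value. Of 14 B lineage genes, 5, 4 and 5 were measured with DAPT, apicidin and shHdac3; 1 rose with DAPT and 3 fell with shHdac3, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.51, 0.70 and 0.18; adjusted p = 0.64, 0.77 and 0.53 with an estimated correlation). Of 14 myeloid genes, 6, 4 and 6 were measured; 1 rose with DAPT, 1 rose with apicidin and 1 fell with shHdac3, likewise adjusted over the list alone (camera adjusted p = 0.22, 0.62 and 0.97; adjusted p = 0.45, 0.77 and 0.98 with an estimated correlation). Its median and mean differ in sign with shHdac3 (-0.04 and 0.08, test down). Itgam, 68.7% of whose exonic bases overlap another gene on the same strand, rose with DAPT (1.04 ± 0.09) and apicidin (0.58 ± 0.07). Of 12 stromal genes, 5, 5 and 6 were measured; 2 rose and 1 fell with DAPT, 2 and 1 with apicidin, and 2 and 3 with shHdac3, or 3 and 1, 2 and 1, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.38, 0.63 and 0.97; adjusted p = 0.56, 0.77 and 0.98 with an estimated correlation). Of 5 measured NK and cytotoxic genes, 2 rose with DAPT (camera adjusted p = 0.054, or 0.45 with an estimated correlation). With shHdac3, 1 rose and 2 fell (camera adjusted p = 0.97, or 0.98 with an estimated correlation). These counts were the same adjusted over the list alone. With shHdac3 the NK test pointed up against a median of -0.17 and a mean of -0.40. Of 12 mitochondrially encoded genes, 0 were among the deposited gene symbols, so 0 were measured.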
